A study of Mus musculus with 2 samples.

How the data were processed

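H3K9me3, a histone mark of silenced chromatin, was profiled by chromatin immunoprecipitation sequencing in the livers of mouse embryos at day 12.5 of development. Per the labels, the embryos were of the strain B6NCrl and of both sexes, and the libraries came from 2 biological replicates, one made from the livers of 120 embryos and one from those of 88. Fragments of 300 to 500 bp were selected, per the labels. The series holds 1 group, so no comparison between conditions was possible. At this stage the mouse liver is a site of blood formation, and its cells include erythroid precursors, hepatoblasts, macrophages, endothelial cells and mesenchymal cells.

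The deposited files were 4 lists of peaks on the mm10 build. Per the file descriptions deposited with them, the authors called 1 list on each replicate's filtered alignments together with a further alignment file, 1 list on both replicates pooled, and derived a list of replicated peaks from the pooled list and the lists of both replicates. The aligner, the peak caller, its threshold and the rule behind the replicated list are not given in the sources used here. Each entry gives the peak's position, its summit, and 4 numbers. The enrichment, a fold over a background, was written by the authors' caller and is the peak's own value, so it was used here to describe, rank or filter peaks within a list. Values of different lists were set side by side, as medians and for single peaks, and in a rank correlation over peaks shared by the replicates, as descriptions with no test. They were also used in checks of the closing section. The p and q values were deposited as −log10 values. The score of each entry, which the authors' caller scales, was not used. The lowest −log10 p in the 4 lists was 2.01, and 24.9% of replicate 1 peaks and 25.2% of replicate 2 peaks had a −log10 q of 2 or more.

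The files hold no read counts, so the depth of each library is unknown and no interval on read counts could be given. Intervals on shares of peaks are 95% Wilson intervals and those on shares of genes are exact 95% binomial intervals. They cover counting error only, and not differences between animals. They also treat peaks or genes as independent, which neighbouring ones are not, so they may be too narrow even for counting error. Reads from amplified libraries are not independent molecules either. Many of the genes described below belong to families with near-identical copies, and how reads that match several copies were placed is not given in the sources used here.

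Peaks were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and tests used scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. Covered length was counted after merging overlapping entries, of which there were 0 in each list. Genes came from GENCODE release M21 and sequence from the GRCm38 assembly, the assembly that mm10 names. Gene, sequence and domain results used chromosomes 1 to 19, X and Y. The replicated list was the main list, with each replicate's own list beside it.

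Peaks of the replicates were called shared where they overlapped by 1 bp or more. Gene features, gene lists, base composition and replicate overlap were tested by circular permutation with 1000 shifts, in which all peaks of a chromosome were moved together by a random distance along the assembled sequence. Shifts keep the spacing of peaks and the clustering of gene families. The p-values are two-sided except for replicate overlap, where they are one-sided, and the smallest value that 1000 shifts can give is 0.001. They describe the positions of peaks in these libraries and are not a replicate error. Values were adjusted by the Benjamini-Hochberg method over the 4 feature classes and over the 20 gene lists. Promoters were taken as 1 kb either side of the start of a protein-coding gene. For each gene list, the excess is the share of its genes whose body held a peak, minus that share over all protein-coding genes, minus the same difference under shifted peaks, in percentage points. Runs of 5 or more replicated peaks no more than 10 kb apart were joined into domains.

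The tests, the gene lists, the rule for naming genes and the alternatives were set before the data were examined, except where a choice is said to have been made later. The gene lists covered zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, Hox, ribosomal protein, histone and Rhox genes, imprinted genes, germline genes, the machinery of H3K9 methylation, and markers of erythroid cells, hepatoblasts, later hepatocytes, macrophages, endothelium, mesenchyme, neurons, cardiac and skeletal muscle, and pancreas. In the erythroid list and in the H3K9 machinery list, 1 symbol each had no gene in the annotation. Named genes are up to 4 members of each list with the most bases covered by replicated peaks among those covered by 200 bp or more in each replicate's list, up to 2 members that no replicated peak touched, the 20 most covered coding genes outside the gene families that were covered by 500 bp or more in each replicate's list, the 10 most enriched and the 5 widest replicated peaks, and the 5 domains with the most covered bases. No test was made for single genes.

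Alternatives were a −log10 q of 2 or more, an enrichment of 4 or more, the pooled list, each replicate alone, overlaps of 50%, equal numbers of top peaks, chromosomes without other sequences, promoters of 2 kb, promoters in place of gene bodies, 200 bp or more of coverage, 10000 random gene lists matched on gene length, last exons in place of gene sides, and joining distances of 5 and 25 kb. Counting merged loci in place of overlapping genes was added after the data were seen. The gene list test was tested on simulated data. Peaks were placed at random in 20 simulations over 21938 coding genes, and 30% of a list of 200 genes were given a further peak. That list was called at an adjusted permutation p under 0.05 in 20 of the 20 simulations, and 1 of 380 unchanged lists was called. All these lists were random genes of 5 kb or more, and the peaks were not clustered. Unlike the peaks of the data, the simulated ones were not scarcer in coding genes than shifted peaks. The simulation therefore does not show how often lists of neighbouring or short genes are called by error where peaks are clustered or scarce in coding genes.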

Results

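Livers of mouse embryos at day 12.5 were profiled for H3K9me3, a histone modification found on silent genes and repeats. The data were 2 biological replicates of 1 group, each a separate pool of embryos, and the question the design poses is where the mark lay in this tissue and how far the replicates placed it in the same intervals. All positions are on mm10. The depth of the libraries is unknown.

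Replicate 1 held 54078 peaks covering 14.9 Mb and replicate 2 held 104388 peaks covering 29.5 Mb, a mean of 22.2 Mb ± 10.3 (SD, n = 2). Replicate 2 thus had 1.93 times as many peaks, while median widths were close, at 229 bp in replicate 1 and 232 bp in replicate 2. The median enrichment was 2.99 in replicate 1 and 2.95 in replicate 2. The pooled list held 131604 peaks over 44.3 Mb. The replicated list held 28461 peaks over 16.3 Mb, with a median width of 468 bp.

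Peaks of the replicates met far more often than shifted peaks did. Of the replicate 1 peaks, 38.8% (20964 of 54078; 95% interval 38.4% to 39.2%) were met by a replicate 2 peak, against a mean of 2.45% and a maximum of 4.35% when peaks were shifted (permutation p = 0.001, one-sided). Of the replicate 2 peaks, 19.9% (20740 of 104388) were met by replicate 1, against 1.27% when shifted (permutation p = 0.001). Both p values are the smallest that the shifts can give. Shared bases came to 4.77 Mb, a Jaccard index of 0.122. Peaks that were met had higher median enrichment than those that were not, 3.03 against 2.82 in replicate 1 and 3.18 against 2.89 in replicate 2. Yet the shared part fell when both lists were filtered by q or by enrichment, which also leaves fewer peaks to meet. At a −log10 q of 2 or more it was 35.4% of replicate 1 and 17.9% of replicate 2 peaks. At an enrichment of 4 or more it was 33.9% and 15.1%. With equal numbers of top peaks, 54078 in each list, replicate 1 kept all its peaks. The shared part was then lower for replicate 1 peaks, at 27.4%, and higher for replicate 2 peaks, at 26.1%. Each stayed above shifted peaks (permutation p = 0.001, one-sided). Across the 20964 shared peaks, which are not independent replicates, the enrichment values of the replicates were weakly related, with a Spearman rho of 0.171, and of 0.271 at a −log10 q of 2 or more. With 50% reciprocal overlap, the shared part was 19.24% of replicate 1 peaks and 9.97% of replicate 2 peaks.

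Every entry of the replicated list was an entry of the pooled list (28461 of 28461). Of these, 19763, or 69.4%, were met at 50% of the shorter interval in both replicates, and 98.8% were met in at least 1 replicate. All 19763 pooled peaks met in both replicates were in the replicated list.

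H3K9me3 was spread unevenly over the chromosomes. Chromosome 5 ranked highest in each replicate and in the replicated list, with 1.46% of its sequenced bases covered by replicated peaks (1.12% in replicate 1 and 1.98% in replicate 2). Chromosomes 7 and 17 followed with 1.12% and 1.01%. Chromosome 14 was the least covered autosome in the replicated list, with 0.306%. Chromosome X stood far below all autosomes, with 0.0857% covered (0.113% in replicate 1 and 0.2003% in replicate 2), and chromosome Y had 0.0118%. Soft-masked repeats make up 96.3% of the sequenced bases of Y, against 46.8% on X. How reads matching several places were treated is unknown, so the Y value does not show that the mark was scarce there. The covered share of X was 0.129 of the autosomal share in the replicated list, and 0.176 ± 0.0134 (SD, n = 2) in the lists of the replicates. Restricting peaks to an enrichment of 4 or more raised the ratio to 0.240.

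**Figure D1:**
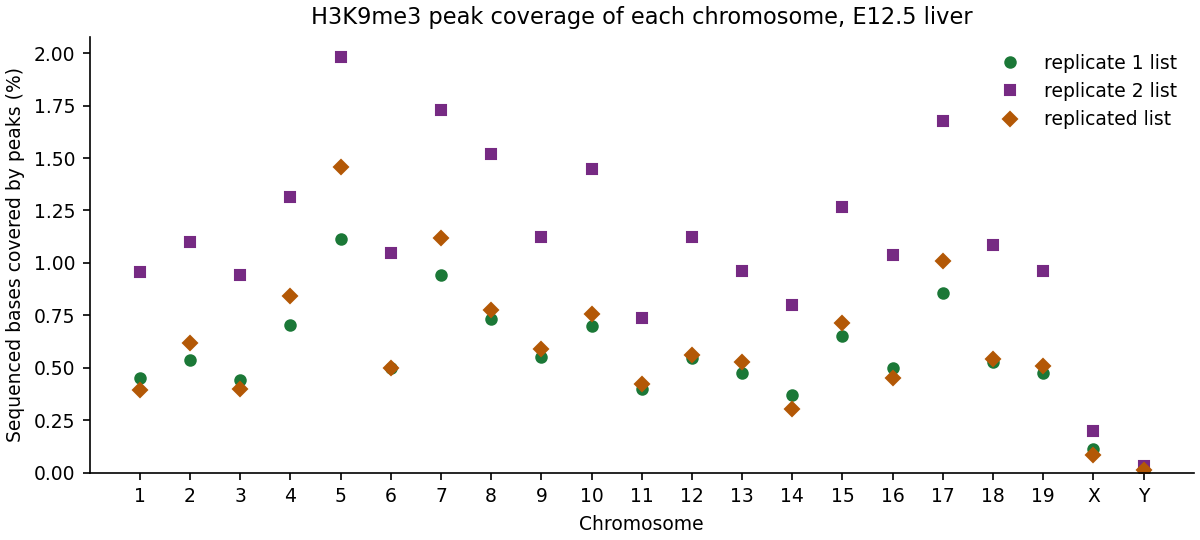
Share of sequenced bases covered by H3K9me3 peaks (y axis, percent) on each chromosome (x axis) in the lists of replicate 1 (circles), replicate 2 (squares) and replicated peaks (diamonds). Chromosome 5 is highest at 1.12%, 1.98% and 1.46%, and X lies at 0.113%, 0.2003% and 0.0857%.

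Relative to protein-coding genes, the covered bases lay mostly outside them. The feature classes used coding genes only, so intergenic sequence here includes noncoding genes and pseudogenes. Intergenic sequence held 67.2% of the bases of replicated peaks, against 57.6% for shifted peaks (adjusted permutation p = 0.00133). Introns held 26.4% against 37.1% (adjusted permutation p = 0.00133), and promoters held 1.31% against 1.70% (adjusted permutation p = 0.00699). Exons held 5.06% against 3.58%, a ratio of 1.41 (adjusted permutation p = 0.00133). The exon value depended on the list, with a ratio of 0.892 in the pooled list (adjusted permutation p = 0.00899) and 0.948 in replicate 2 alone (adjusted permutation p = 0.227), against 3.84 among peaks with an enrichment of 4 or more (adjusted permutation p = 0.004). Among those peaks the promoter ratio was 1.27 (adjusted permutation p = 0.212) and the intergenic ratio 0.957 (adjusted permutation p = 0.350).

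Called peaks were rich in G and C and held less annotated repeat sequence than shifted peaks. The GC content of replicated peaks was 47.1%, against 42.1% for shifted peaks (permutation p = 0.001), with 46.9% in replicate 1 and 46.3% in replicate 2. Soft-masked repeat sequence made up 29.5% of their bases, against 33.7% for shifted peaks (permutation p = 0.001), with 28.9% in replicate 1 and 29.3% in replicate 2. How reads matching several places were treated is unknown, and peaks cannot be called where such reads were dropped, so this share describes the called peaks and does not show that the mark avoids repeats.

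Of the 20 gene lists, 5 were touched by replicated peaks more than shifted peaks allowed, relative to all protein-coding genes. These were the clustered protocadherin, imprinted, zinc finger, vomeronasal receptor and olfactory receptor genes. Over all 21938 coding genes, 14.6% had a peak in the gene body, below the 18.5% of shifted peaks (adjusted permutation p = 0.005). That test was chosen after results had been seen and was adjusted over the 15 gene-type classes of the closing section. The same 5 lists were called against 10000 random lists of coding genes matched on length. Unlike shifts, random lists ignore the clustering of gene families, so these calls overstate the evidence.

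**Figure D2:**
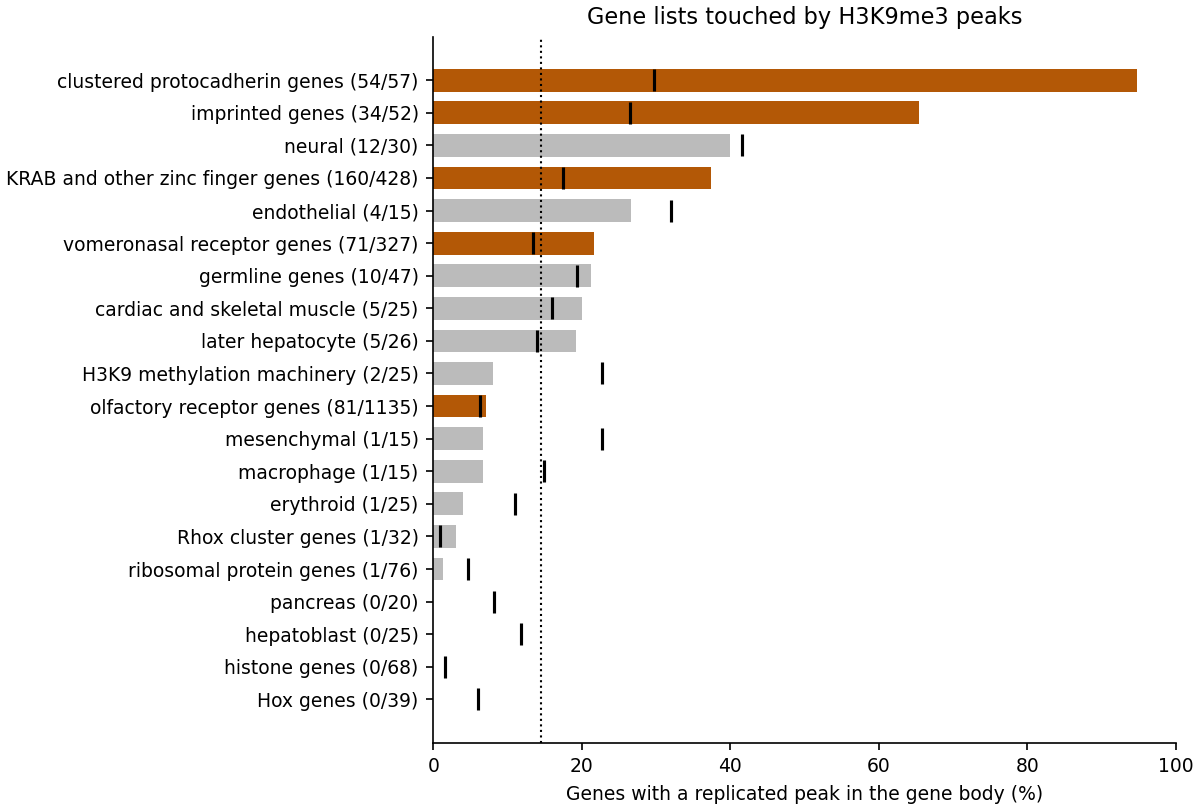
Share of the genes of each list with a replicated peak in the gene body (bars; x axis in percent, genes touched and total in brackets on the y axis), with the mean share under shifted peaks (black ticks) and the share of all coding genes (dotted line, 14.6%). Orange bars are lists with an adjusted permutation p under 0.05, led by clustered protocadherin genes at 94.7% and imprinted genes at 65.4%.

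Zinc finger genes, most of which encode DNA-binding repressors of transposons and genes, were touched in 160 of 428 cases, 37.4% against 17.4% for shifted peaks, an excess of 23.9 points (adjusted permutation p = 0.005). The count was 172 in replicate 1 and 212 in replicate 2. Zfp936 (chromosome 7, 43114229 to 43192109) had 16.2 kb covered by 25 replicated peaks, with 10.1 kb in replicate 1 and 15.3 kb in replicate 2. Zfp873 (chromosome 10, 82048123 to 82064745) had 65.0% of its length covered, and its strongest peak, 82058756 to 82062483, had its summit in a coding exon at an enrichment of 5.97. Zfp110 on chromosome 7 had 63.5% of its length covered and Zfp981 on chromosome 4 had 35.3%. Rsl1 and Rslcan18, on chromosome 13, had no peak in either replicate. On chromosome 7, which has the most zinc finger genes, 39 of 104 were touched, followed by 18 of 47 on chromosome 17, 20 of 43 on chromosome 13 and 15 of 32 on chromosome 4. Among chromosomes with 10 or more zinc finger genes, the share ran from 1 of 11 on chromosome 18 to 13 of 20 on chromosome 9. At an enrichment of 4 or more the excess was 13.6 points (adjusted permutation p = 0.00666).

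Within zinc finger genes, peaks gathered toward the 3′ end, where the last exon encodes the zinc fingers. Of the 160 genes with peaks, 131 (81.9%; exact 95% interval 75.02% to 87.5%) had more covered bases 3′ of the midpoint than 5′ of it, against 49.9% for shifted peaks (exact binomial p = 1.1e-16, and permutation p = 0.001 from the shifts). The share was 80.8% in replicate 1 and 79.7% in replicate 2. By density per base, the last exon exceeded the rest of the gene in 119 of 160 genes, 74.4% against 17.7% for shifted peaks. Neighbouring zinc finger genes are not independent, so the binomial value overstates the evidence. With an enrichment of 4 or more, 56 of 68 genes leaned 3′, with an exact binomial p of 6.21e-08, while the shifts gave a permutation p = 0.0649. Promoters of zinc finger genes had no excess, with 10 of 428 touched and a difference of 0.130 points (adjusted permutation p = 1).

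**Figure D3:**
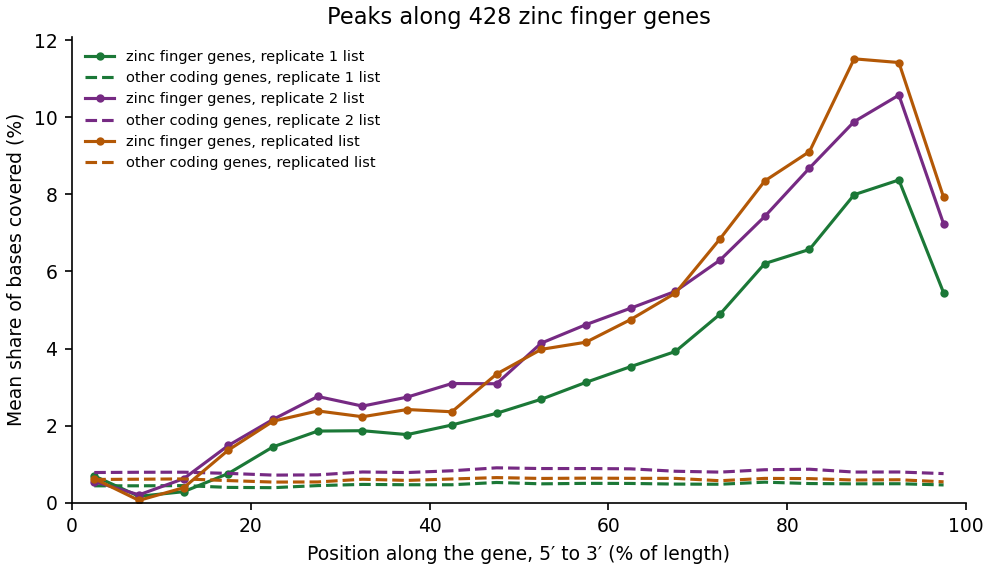
Mean share of bases covered by peaks (y axis, percent) in 20 bins along the gene body from 5′ to 3′ (x axis, percent of gene length) for 428 zinc finger genes (solid lines) and all other coding genes (dashed lines), in the lists of replicate 1 (green), replicate 2 (purple) and replicated peaks (orange). In replicated peaks, zinc finger genes rise from 0.628% in the first bin to 11.5% in bin 18, and other coding genes stay between 0.538% and 0.654%.

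The clustered protocadherins, cell surface proteins whose variable exons give neurons distinct identities, lie on chromosome 18 and were touched in 54 of 57 cases in each replicate and in the replicated list (94.7% against 29.8% for shifted peaks; adjusted permutation p = 0.005). Many of these gene models overlap and share 3′ exons. When they were merged, 23 of 23 separate loci were touched. Pcdha1 (36930184 to 37187661) had 25.6 kb covered by 45 peaks, with 17.5 kb in replicate 1 and 29.3 kb in replicate 2. Pcdhga1 (37661793 to 37841873) had 22.2 kb covered, and its strongest peak lay at a promoter at 37755841 to 37756724. Pcdhgc3 and Pcdhgc4, at the 3′ end of the gamma cluster, had no peak in either replicate. Promoters in the clusters were touched in 39 of 57 genes.

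Imprinted genes, expressed from the allele of 1 parent, were touched in 34 of 52 cases, 65.4% against 26.5% for shifted peaks (adjusted permutation p = 0.005), with 34 in replicate 1 and 37 in replicate 2. Their promoters were touched in 17 of 52 cases, 32.7% against 3.05% (adjusted permutation p = 0.00666). At Peg3, a paternally expressed zinc finger gene on chromosome 7, a peak of 4234 bp (6727043 to 6731276; enrichment 5.18) covered the promoter. At Gnas on chromosome 2, a peak of 3714 bp (174283972 to 174287685) overlapped the start of the gene model, and 10.5 kb of the gene was covered (6.32 kb in replicate 1 and 10.2 kb in replicate 2). All 19 peaks counted in Kcnq1 on chromosome 7 also lay in Kcnq1ot1, the overlapping antisense transcript. Ascl2 and Copg2 had no peak in either replicate.

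Vomeronasal receptor genes, expressed in pheromone-sensing neurons, were touched in 71 of 327 cases, 21.7% against 13.5% for shifted peaks, an excess of 12.1 points (adjusted permutation p = 0.005), with 88 in replicate 1 and 119 in replicate 2. Vmn2r60 on chromosome 7 had 6.26 kb covered (5.11 kb in replicate 1 and 7.67 kb in replicate 2). Vmn1r42 and Vmn1r43 on chromosome 6 overlap and shared their strongest peak, 89861029 to 89862493. Olfactory receptor genes were touched in 81 of 1135 cases, below the 14.6% of all coding genes, yet 7.14% against 6.28% for shifted peaks, with 141 in replicate 1 and 261 in replicate 2. Set against the difference between these genes and coding genes under shifted peaks, the excess was 4.78 points (adjusted permutation p = 0.0480). The size of the olfactory excess depended on the list, with 10.8 points in replicate 1 alone, 17.7 in replicate 2 alone and 20.5 in the pooled list, and the vomeronasal excess was 15.1, 18.2 and 21.2 points in these lists. The larger part of each of these values came from coding genes, which were touched less than under shifts. In the same order, coding genes were touched at 18.7%, 26.4% and 27.7%, against 27.5%, 38.6% and 40.6% for shifted peaks. Olfactory genes were touched at 12.4%, 23.0% and 27.4%, against 10.4%, 17.5% and 19.8%. Vomeronasal genes were touched at 26.9%, 36.4% and 40.7%, against 20.5%, 30.3% and 32.4%. Olfr769 on chromosome 10 had 3.01 kb covered and Olfr1349 on chromosome 7 had 2.86 kb. Both receptor calls ended with an enrichment of 4 or more, where the excess was −0.107 points for vomeronasal genes (adjusted permutation p = 0.989) and −0.593 points for olfactory genes (adjusted permutation p = 0.195). The olfactory call also ended at a −log10 q of 2 or more (adjusted permutation p = 0.0733) and with 200 bp or more covered (adjusted permutation p = 0.0559). With promoters in place of gene bodies both calls ended, at 1.61 points for vomeronasal genes (adjusted permutation p = 0.959) and 0.192 points for olfactory genes (adjusted permutation p = 1).

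Germline genes, needed in germ cells and silent in most other tissues, were touched over the gene body in 10 of 47 cases, 21.3% against 19.3% for shifted peaks (adjusted permutation p = 0.476), with 17 in each replicate. Their promoters were touched in 6 of 47 cases, 12.8% against 2.48% (adjusted permutation p = 0.00666), with 13 in replicate 1 and 10 in replicate 2. The genes, listed after this count was seen, were Ddx4, Dazl, Taf7l, Sycp2, Brdt and Sycp1, which include an RNA helicase of germ cells and components of the meiotic synaptonemal complex. The Ddx4 promoter on chromosome 13 had a peak of 1367 bp (112651548 to 112652914) at an enrichment of 4.09. In the list of replicate 1 alone the gene bodies also passed the test (excess 14.8 points, adjusted permutation p = 0.04995), and in that of replicate 2 they did not (4.94 points). Asz1 and Ddx25 had no peak in either replicate.

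None of the lists of marker genes of fetal liver cell types passed the test. Replicated peaks touched 0 of 25 hepatoblast genes, among them Afp and Ahsg, which encode secreted liver proteins, and 1 of 25 erythroid genes, an intron of Ank1 with 451 bp covered. In the lists of the replicates, 1 and 4 hepatoblast genes were touched. The adjusted permutation p was 0.440 for hepatoblast and 0.736 for erythroid genes. The counts were 1 of 15 for macrophage, 4 of 15 for endothelial and 1 of 15 for mesenchymal genes, with adjusted permutation p values of 0.751, 0.875 and 0.370. The macrophage list had 1 gene touched in replicate 1 and 2 in replicate 2, the endothelial list 4 and 9, the mesenchymal list 3 and 7, and the erythroid list 2 in each. Adgre1 had 643 bp covered, Flt1 had 1783 bp and Reln had 310 bp. Genes of later hepatocytes were touched in 5 of 26 cases (adjusted permutation p = 0.370), with 6 in replicate 1 and 7 in replicate 2. Among them Cyp2c29, a cytochrome P450 gene on chromosome 19, had 4.08 kb covered (1.81 kb in replicate 1 and 5.50 kb in replicate 2), Sult2a8 had 2.09 kb and Cyp3a11 had 2.06 kb.

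Genes of other tissues did not pass the test either. Neural genes were touched in 12 of 30 cases, 40.0% against 41.6% for shifted peaks (adjusted permutation p = 0.736), with 12 in replicate 1 and 17 in replicate 2. They include very long genes such as Csmd1 on chromosome 8, with 21.1 kb covered in a body of 1643 kb. Muscle genes were touched in 5 of 25 cases (adjusted permutation p = 0.427) and in 6 in each replicate, with 32.0 kb covered in Ttn, the gene of the giant sarcomere protein titin, and 664 bp in Ryr1. The strongest Ttn peak, chromosome 2 at 76708467 to 76713096, spanned 4630 bp with its summit in a coding exon. Pancreas genes were touched in 0 of 20 cases (adjusted permutation p = 0.551) and Hox genes in 0 of 39 (adjusted permutation p = 0.751), with 0 of each in replicate 1 and with 2 pancreas and 4 Hox genes in replicate 2. Histone genes were touched in 0 of 68 cases (adjusted permutation p = 0.370), ribosomal protein genes in 1 of 76 (Rpl3, adjusted permutation p = 0.875) and Rhox genes in 1 of 32 (Rhox13, adjusted permutation p = 0.0699), with the same counts in each replicate. Of the genes of the H3K9 methylation machinery, 2 of 25 were touched (adjusted permutation p = 0.370), with 4 in replicate 1 and 6 in replicate 2, among them Atf7ip, which encodes a partner of the H3K9 methyltransferase SETDB1, with 4.09 kb covered.

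Part of the mark lay in long runs of peaks. Joining replicated peaks gave 744 domains that held 8572 peaks, or 30.4% of those on chromosomes, with a median length of 22.1 kb. Chromosome 7 had 122 domains, chromosome 5 had 111 and chromosome 4 had 77. The domain with the most covered bases was 521 kb long, on chromosome 5 from 125604786 to 126125593, and began inside Tmem132b, which encodes a transmembrane protein. It held 261 replicated peaks and 216 kb of covered bases (126 kb in replicate 1 and 184 kb in replicate 2). The next, on chromosome 5 from 127732323 to 128133598, lay at Tmem132d with 186 peaks. The others were on chromosome 5 from 116745012 to 117043034, with only noncoding genes, on chromosome 4 from 152638930 to 152953659, also with only noncoding genes, and on chromosome 2 from 171864170 to 172179788, which contains Cbln4. The number of domains depended on the list, with 1574 in replicate 1, 3981 in replicate 2, 5484 in the pooled list and 17 at an enrichment of 4 or more.

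**Figure D4:**
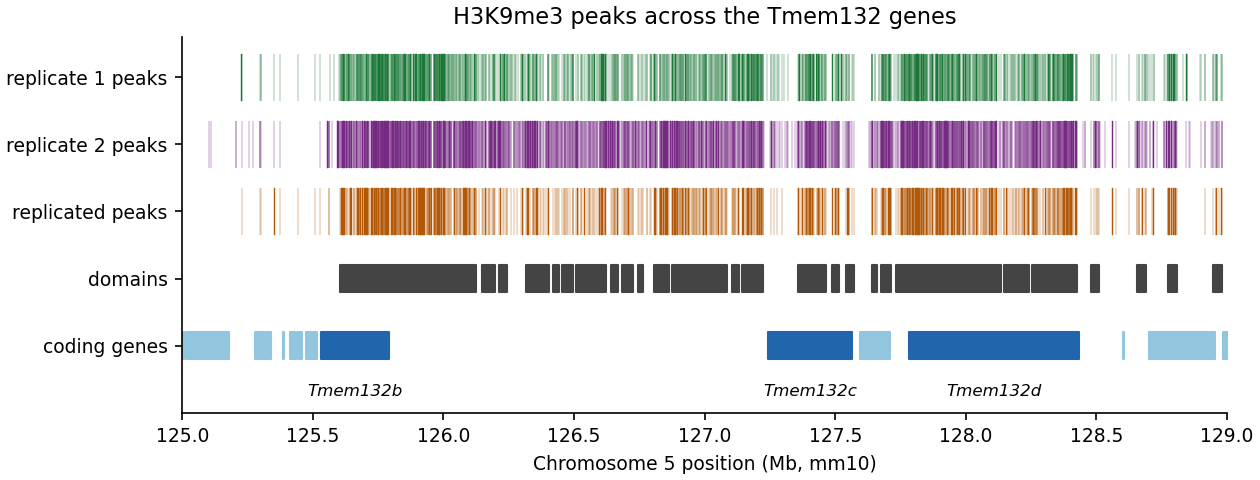
Positions of H3K9me3 peaks on chromosome 5 from 125 to 129 Mb (x axis, Mb) in the lists of replicate 1 (1421 peaks), replicate 2 (2033) and replicated peaks (1002), with joined domains (26, black) and coding genes (blue, with the Tmem132 genes in dark blue). Peaks are dense from Tmem132b on, across the stretch without coding genes that follows it, and over Tmem132d.

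The most covered coding genes outside the listed families were long genes. Tmem132d (chromosome 5, 127781630 to 128433077) led with 194 kb covered by 280 peaks, 29.7% of its length, with 116 kb in replicate 1 and 178 kb in replicate 2. Cdh13, a cadherin gene on chromosome 8, had 129 kb covered in a body of 1041 kb. Tmem132b had 92.2 kb and Tmem132c 43.4 kb. Chromosome 5 also held Caln1 with 56.1 kb, Mtus2 with 49.7 kb, Galnt17 with 47.6 kb and Sdk1, a cell adhesion gene, with 47.5 kb. Elsewhere Csmd2 had 54.1 kb covered, Ptprt 52.5 kb, Alk, a receptor tyrosine kinase gene, 44.9 kb, Adcy2 34.4 kb, Cdh4 33.2 kb and Tmem117 32.0 kb. Gm42416, Gm37013 and Gm37388 span the protocadherin clusters of chromosome 18, and their covered bases are largely those of the clusters. Gm20388, on chromosome 8, is a gene model of 4435 kb with 32.6 kb covered. Mroh2a on chromosome 1 stood out as a short gene of 35.3 kb, of which 81.3% was covered (28.7 kb, with 25.9 kb in replicate 1 and 27.0 kb in replicate 2). Its strongest peak had an enrichment of 3.24, near the median of 3.03 of the replicated list.

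The peak of highest enrichment lay on chromosome X from 170674119 to 170678136, in an intron of Asmt, a gene of melatonin synthesis in the pseudoautosomal region, with an enrichment of 14.3 (12.1 in replicate 1 and 13.3 in replicate 2). Of the other 9 most enriched peaks, 3 lay on sequences outside the assembled chromosomes and 1 on chromosome Y from 258991 to 259551. A peak at 10.01 on chromosome 7, 5028735 to 5032563, had its summit in a coding exon and touched the bodies of Gm44973, Zfp865 and Ccdc106, and another at 9.51 on chromosome 5, 137109926 to 137115397, in a coding exon of Trim56. Intergenic sequence 17.3 kb from Znrf4 on chromosome 17 held a peak at 8.65, with 4.38 in replicate 1 and 9.54 in replicate 2. An intron of Crlf2 on chromosome 5 held a peak at 8.43 and a coding exon of the zinc finger gene Zfp180 on chromosome 7 held one at 8.13, with 4.20 in replicate 1 and 8.94 in replicate 2. Of the 5 widest peaks, 2 lay in Mroh2a, including the widest with 10352 bp (chromosome 1, 88225464 to 88235815), and the others in Plec, which encodes the cytolinker plectin (9798 bp), in Il3ra (8973 bp) and in an intron of Nphp4 (8934 bp). The 2 Mroh2a peaks were weak, with enrichments of 2.20 for the widest and 2.82, against 7.26 in Plec, 7.02 in Il3ra and 7.02 in Nphp4.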

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

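The patterns in this part were seen in the data before any explanation was tested. The tests of the p threshold, of enrichment steps, of mean enrichment, of X by p value and of merged gene models were chosen only after results had been seen. The series has 1 group, so no biological explanation was tested.

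Replicated peaks also lay on sequences outside the assembled chromosomes, which no gene comparison used. There were 223 such peaks on 20 sequences, with 327 in the list of replicate 1 and 349 in that of replicate 2. No control sample was used here. Their median enrichment was 3.24, against 3.03 for those on chromosomes.

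Chromosome X was covered at 0.129 of the autosomal share. Repeat content and base composition are argued against as the whole cause, because autosomal windows of 1 Mb matched to 154 X windows on both were covered far more, with a ratio of X to matched windows of 0.0738 in the replicated list and at most 0.118, in replicate 1. A lower copy number of X in pools of both sexes remains open. Comparing X at an enrichment of 3 or more with autosomes at 4 or more gave 1.33 in replicate 1 but 0.663 in the pooled list and 0.698 in replicate 2, where that explanation needs a ratio near 1 and a ratio below 0.5 in all 3 lists would have excluded it. Comparing the density of peaks at a −log10 p of 7.5 or more on X with that at 10 or more on autosomes gave 0.822 in replicate 1, 0.355 in the pooled list and 0.751 in replicate 2, which decides no more.

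Replicate 2 had 1.93 times the peaks of replicate 1. With more reads behind replicate 2 a lower enrichment would reach the same p, yet at a −log10 p of 4 to 5 the median enrichment of replicate 2 was 0.976 of that of replicate 1 and the mean 1.02, both above the limit of 0.95 set for this explanation. Enrichment values come in steps, so the ratio of medians is coarse. The step was 0.227 in replicate 2, 0.217 in replicate 1 and 0.119 where the reads were pooled. How the caller derived enrichment and p from the replicate's reads and the further alignment file is unknown. These values therefore do not decide whether more reads lay behind replicate 2, and that stays open. A looser threshold is argued against, since the smallest −log10 p differed by 0.0422. A difference in the immunoprecipitation or between the pools of embryos was not tested and stays open too.

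For 5 gene lists the difference from coding genes exceeded that under shifted peaks, although olfactory receptors were touched less often than coding genes, 7.14% against 14.6%. Against random lists matched on length, 5 of the 5 lists were called, but random lists ignore the clustering of families, which makes their p-values too small. By shares, protocadherin, imprinted, zinc finger and vomeronasal genes were touched at 94.7%, 65.4%, 37.4% and 21.7%. Their matched lists were touched at 25.9%, 20.4%, 12.3% and 8.42%, which argues against gene length as the whole cause for these genes. For olfactory receptors, at 7.14% against 4.87%, the comparison does not decide. Overlapping gene models counted more than once are argued against, since with genes merged into loci the excess over the shifted difference was still called for 5 of the 5. Among these, olfactory loci were touched at 7.25% against 15.7% of coding loci (excess 5.09 points, adjusted permutation p = 0.0400), and the adjusted permutation p was 0.005 for each of the others. Reads shared between near-identical copies of these genes were not tested, and remain open.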

How the results depend on the processing

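Merging overlapping genes into loci was chosen after seeing the data; the other alternatives were set before. Values without a test were held to a band around the main value. It was an interval or the SD of the replicates, and for peak numbers and covered lengths a fixed fold of the main value. Of 269 alternative values for 41 results, 202 kept the direction and the side of the threshold, or stayed within that band. For 9 results every alternative did so: the GC content (46.3% to 48.0%), the soft-masked share (28.1% to 29.6%), the intron ratio (0.658 to 0.781), the 3′ share of zinc finger genes by the exact binomial test (79.3% to 82.4%, though the shifts gave a permutation p of 0.0649 at an enrichment of 4 or more), the part of the replicated list met in both replicates (70.0%), the protocadherin (49.9 to 95.5 points) and imprinted lists (30.5 to 45.0), and the erythroid and hepatoblast lists, which passed the test in none. The alternative of last exons for zinc finger genes is another measure, at 74.4% against 17.7% for shifted peaks. Lists called numbered 5 in the main setting, 4 both at a −log10 q of 2 or more and with 200 bp or more covered, and 6 without replicate 2. They numbered 3 at an enrichment of 4 or more, where the zinc finger, protocadherin and imprinted lists were called. For promoters they also numbered 3, the protocadherin, imprinted and germline lists. No paired analysis was possible because the series has 1 group. Depth is unknown, so what it limits could not be measured. Except where fewer peaks passed a filter, the cause was not tested.

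At a −log10 q of 2 or more, peak numbers were 13492 (replicate 1), 26324 (replicate 2) and 65105 (pooled), covering 4.92, 9.90 and 26.3 Mb. Spearman's rho was 0.271, the olfactory excess 3.95 points (adjusted permutation p = 0.0733) and the neural one −0.506. With 200 bp or more covered, the olfactory excess was 4.60 (adjusted permutation p = 0.0559).

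At an enrichment of 4 or more, peaks numbered 2356, 5288, 1982 (pooled) and 1966 (replicated), covering 1.22, 2.81, 2.01 and 2.00 Mb, with 17 domains and an X ratio of 0.240. The promoter ratio was 1.27 and the intergenic ratio 0.957. Excess values changed sign for olfactory (−0.593), vomeronasal (−0.107), ribosomal protein (−0.637), histone (−0.361), Rhox (−0.333), later hepatocyte (−1.76), endothelial (2.03) and neural genes (−7.58).

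In the pooled list, the X ratio was 0.159, the exon ratio 0.892, domains numbered 5484, and the excess was 20.5 for olfactory, 21.2 for vomeronasal, −0.925 for ribosomal protein, 9.71 for macrophage, 3.07 for mesenchymal and 4.67 for pancreas genes.

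Shared peaks came to 31.0% of replicate 1 and 15.6% of replicate 2 at 50% of the shorter interval, and to 19.24% and 9.97% at 50% reciprocal overlap, where rho was 0.252.

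For promoters in place of gene bodies, the excess was 0.130 for zinc finger, 0.192 for olfactory, 1.61 for vomeronasal, 11.1 for germline (adjusted permutation p = 0.00666), −2.0 for ribosomal protein, −1.14 for histone, −2.18 for later hepatocyte, −1.55 for neural, −1.70 for muscle and 2.35 for H3K9 machinery genes. Against length-matched lists it was −2.74 for ribosomal protein, −3.20 for histone, −1.84 for Rhox and 2.76 for endothelial genes.

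With either replicate left out, ranges were 0.166 to 0.185 for the X ratio, 0.948 to 1.19 for the exon ratio and 1574 to 3981 for domains. The excess ranged from −1.46 to 5.36 for Hox, −9.84 to 12.6 for endothelial, −5.29 to 11.2 for mesenchymal, 10.8 to 17.7 for olfactory and 15.1 to 18.2 for vomeronasal (both called without either replicate), −0.692 to 10.99 for neural, −4.26 to 1.01 for pancreas and 4.94 to 14.8 for germline genes, the last passing the test without replicate 2 (adjusted permutation p = 0.04995).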

Other observations

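The tests of gene families and of gene types in this part, the number of shifts used for the families, and the tests of the 20 most covered genes were chosen only after results had been seen.

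Beyond the listed families, 243 groups of 10 or more coding genes with a common symbol stem were tested. A first run with 1000 shifts called 0 of them after adjustment, with 18 at an unadjusted permutation p under 0.05 and a lowest adjusted permutation p of 0.121. The number of shifts was then raised to 10000, and 2 groups passed, with 16 at an unadjusted p under 0.05. Both had the smallest unadjusted p that these shifts can give, 1e-04, and because the number was raised after the first run they are candidates only. Secretoglobin genes (Scgb), which encode small secreted proteins of glands, were touched in 11 of 34 cases, 12 in replicate 1 and 11 in replicate 2, an excess of 32.2 points (adjusted permutation p = 0.0121). Keratin-associated protein genes (Krtap), expressed in hair, were touched in 7 of 57 cases, but in 3 in replicate 1 and 16 in replicate 2. Their share of 12.3% was below the 14.6% of all coding genes. The excess of 14.8 points (adjusted permutation p = 0.0121) is relative to the difference between these genes and coding genes under shifted peaks. The groups next in order of p did not pass. They were the Alg genes of protein glycosylation, touched in 5 of 12 cases (adjusted permutation p = 0.154), the semaphorins (Sema), touched in 2 of 20 with an excess of −23.4 points (adjusted permutation p = 0.267), the Skint genes of chromosome 4, touched in 9 of 11 (adjusted permutation p = 0.348), the sulfotransferases (Sult), touched in 11 of 21 (adjusted permutation p = 0.348), and the Nlrp genes, several of which act in oocytes, touched in 9 of 17 (adjusted permutation p = 0.566).

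Gene types were compared with shifted peaks in 15 classes, made of 8 types over all genes and, except for coding genes, outside coding genes, and 6 classes passed after adjustment over the 15. Processed pseudogenes, which are copies of spliced transcripts, were touched in 361 of 9940 cases, 3.63% against 1.33% for shifted peaks, a ratio of 2.74 (adjusted permutation p = 0.005). The share was 4.64% in replicate 1 and 7.78% in replicate 2. Among the 7788 outside coding genes the ratio was 3.14 (adjusted permutation p = 0.005). Unprocessed pseudogenes were touched in 129 of 2642 cases, a ratio of 1.59 (adjusted permutation p = 0.00749), and in 120 of 2483 cases outside coding genes, a ratio of 1.60 (adjusted permutation p = 0.00749). Coding genes were touched less than shifted peaks allowed, with a ratio of 0.788 (adjusted permutation p = 0.005). Antisense genes had a ratio of 0.836 (adjusted permutation p = 0.00749), but the 209 of them outside coding genes had 18 touched and a ratio of 1.34 (adjusted permutation p = 0.341). Long intergenic noncoding genes had a ratio of 1.00 (adjusted permutation p = 1), and no class of microRNA, small nuclear RNA or ribosomal RNA genes passed.

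A candidate explanation for the position of peaks in zinc finger genes is a 3' position common to all coding genes with peaks. Among length-matched lists of other multi-exon coding genes with peaks, a mean of 55.1% leaned 3', and the zinc finger share of 81.9% lay at percentile 100 of these lists. That explanation is argued against as the whole cause, and what sets the position was not tested.

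Whether gene length alone may account for the very long genes among the most covered stays open. Over all genes of 300 kb or more, 0.673% of bases were covered, against 0.633% for shifted peaks, a ratio of 1.06 (permutation p = 0.545), but this mean over 567 genes does not bear on the few that lead, such as Tmem132d with 29.7% of its length covered. The 20 most covered coding genes were therefore picked in the same way under each shift, which keeps the spacing of peaks. Of the 20, 17 were of 300 kb or more, against a mean of 12.3 under shifts (permutation p = 0.0330), and together they held 1317 kb of covered bases against 952 kb (permutation p = 0.0110). Counting overlapping genes once, since 3 of the leading gene models span the protocadherin clusters, gave 16 genes against 12.3 (permutation p = 0.112) and 1163 kb against 947 kb (permutation p = 0.129). After adjustment over the 6 values computed, none passed, with a lowest adjusted p of 0.0659.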
